A study of Mus musculus with 208 samples.

How the data were processed

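RNA was sequenced from lung, liver and kidney of male C57BL/6J and CAST/EiJ mice that breathed 1,3-butadiene (BD) or clean air. Of the 208 samples of the series, the 70 RNA libraries were used, 37 of CAST/EiJ and 33 of C57BL/6J. The 68 ATAC and 70 H3K27ac samples were not analysed here. The authors deposited 1 table of expected counts per gene, a unit that need not be whole. Per the submitters' processing notes, STAR and RSEM were the tools and mm9 was the genome build; their versions, the strand setting and the gene annotation are not given in the sources used here. Per the labels, RNA was extracted with a column kit and made into polyA libraries.

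The table held 24485 gene symbols. A median of 8.28% of a library's values were not whole, and all were rounded to whole numbers. A total of 62 genes had no value in any CAST/EiJ library and were left out, so 24423 genes were used. No reference genome was used here; gene names were checked against mouse gene tables, where 23998 symbols were current and 24403 were current or older symbols. The labels give 1 genome build for both strains; whether CAST/EiJ reads were counted on an adjusted genome or another gene set is not given in the sources used here, and the 62 genes leave that open. Reads shared between paralogs were divided by the authors' software in a way that was not examined here. No pair of the 70 libraries was alike within sampling noise: over 2415 pairs the lowest chi-square per degree of freedom was 4.91.

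Groups came from the labels of strain, tissue and treatment. Each tissue was fitted with its 4 strain by treatment groups in 1 model with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr on the groups, the quasi-likelihood F test, and Benjamini-Hochberg adjustment over the genes of each contrast with a threshold of 0.05. The contrasts were BD against clean air in each strain, the difference of these changes between strains, and CAST/EiJ against C57BL/6J in clean air. A model per strain over all 3 tissues tested whether the BD change differed between tissues. The p-values given are from these fits unless another test is named, and log2 changes and standard errors are edgeR's. CPM values are scaled by TMM over the filtered genes unless named here. Plain CPM was used for averages of the 9 tissue identity markers over all libraries of a tissue. It was also used for the Krt13, Krt4, Alb and Kap values that compare lung libraries. The share of kidney transcripts in liver is scaled over all genes.

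A total of 41 gene and marker lists, the tests, the named-gene rule and most alternatives were fixed before the data were examined. Lists were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, and again with an estimated correlation, adjusted over the lists of all BD or all strain comparisons. Under the estimated correlation, 3 of 93 list calls held: NRF2 targets in the lungs of both strains and proximal tubule markers in CAST/EiJ liver. The list test fry of limma, also planned, called 12 and 6 lists for BD in C57BL/6J and CAST/EiJ lung. In liver it called 4 and 3 and in kidney 1 and 3, in the same order. For the strain differences it called 24 lists in lung, 16 in liver and 20 in kidney. Genes were picked by rule, and the text gives part of them. For each BD comparison, among genes with an adjusted p under 0.05 and a mean of at least 1 CPM, these were the 8 largest rises and 8 largest falls, and for each list up to 3 members with the smallest adjusted p under 0.05. For the interaction of strain and BD these were the 5 smallest adjusted p in each direction, for strain differences the 6 largest in each direction, and for the tissue interaction the 6 smallest. Cyp2e1, Ephx1, Cdkn1a, Mgmt, the members of the BD metabolism list and the identity markers were looked up whatever their p. 1 of the genes picked was left out on purpose and is not reported here.

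The alternatives fixed in advance were DESeq2 1.42.0, RLE scaling, no low-count filter, 1 surrogate variable from sva 3.50.0, only mice numbered under 100, each library left out in turn, and the mouse as a replicate block in the tissue interaction. The number set as a covariate, fits within each set, and liver without libraries above 25% Rn45s were added after seeing the data. Titles carry a number that recurs across tissues and was read as the mouse. As a check, residuals of liver and kidney with the same number had a median r of 0.24 in each strain and were above 0.1 in 10 of 11 C57BL/6J and 10 of 12 CAST/EiJ pairs; for lung and kidney this held in 6 of 11 and 5 of 12, and for lung and liver in 6 of 11 and 5 of 11. The best match in the other tissue was the same number in 3 of 11 and 3 of 12 for liver and kidney, 3 of 11 and 1 of 12 for lung and kidney, and 2 of 11 and 1 of 11 for lung and liver. Number sets shared across tissues also give a positive r, so the pairing rests on the titles. For random regroupings, treatment was relabelled within strain with mice kept together, 100 splits in all with the real one. For strain differences, strain was relabelled among the clean-air libraries of a tissue, also in 100 splits.

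The tests were tried on simulated data made from these counts, with changes placed in the C57BL/6J groups. Of genes changed 1.5, 2 and 4 times, lung gave back 61.2, 85.1 and 98.5%, liver 26.9, 77.6 and 97%, and kidney 53.7, 80.6 and 100% by edgeR. Of edgeR's calls 3 of 166, 8 of 142 and 10 of 166 were false, and of DESeq2's 21 of 186, 22 of 170 and 30 of 196. The changed genes were drawn only from those with a mean of at least 1 CPM, while the real tests also cover lower genes. The simulated counts held no strain difference, no number sets and no correlation between genes. These rates therefore need not hold in the real data. Figures were drawn with matplotlib 3.10.9.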

Results

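The study exposed male mice of the inbred strains C57BL/6J and CAST/EiJ to clean air or to 1,3-butadiene (BD), an inhaled industrial gas and genotoxic carcinogen that cells oxidise to reactive epoxides. Exposure lasted 6 hours a day on weekdays for 2 weeks. The stated purpose was to find strain-specific chromatin and expression differences and how they respond to BD. RNA sequencing of lung, liver and kidney is described here, in 70 libraries of 12 groups. Lung held 6 BD and 5 clean-air libraries of C57BL/6J and 5 BD and 7 clean-air libraries of CAST/EiJ. Liver held 6 and 5 of C57BL/6J and 6 and 6 of CAST/EiJ. Kidney held 6 and 5 of C57BL/6J and 6 and 7 of CAST/EiJ. Total counts per library, in megacounts, ran from 8.14 to 41.6 in lung (median 15.4), 12.2 to 42.1 in liver (median 20.8) and 9.01 to 39.8 in kidney (median 19.8).

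Each library carried the transcripts of its labelled tissue. Sftpc, a surfactant protein of alveolar type II cells, averaged 9700 ± 1720 CPM (counts scaled to library size, with SD) in the 23 lung libraries. Alb, the plasma protein albumin, averaged 44300 ± 11800 CPM in the 23 liver libraries. Umod, made in the thick ascending limb of the nephron, averaged 4840 ± 838 CPM in the 24 kidney libraries. Rn45s, the ribosomal RNA precursor, took up to 15.2% of counts in lung, 45.3% in liver and 19.2% in kidney. The mice also fell into a pair of sets by their number: set A (1 to 5, 7 to 9 and 13 to 15) and set B (6, 10 to 12, 16 to 18 and the clean-air mice titled RNA_101 to RNA_106). With strain and treatment in the model, 1669 genes in lung, 2642 in liver and 3818 in kidney differed between the sets. The sets were drawn from these same libraries, so the counts are not an independent test of them. No label explains the sets and they were found in the data, so BD changes are also given within each set. In CAST/EiJ the clean-air mice of set A were only mice 1 and 2, and in C57BL/6J those of set B were only mice 6 and RNA_106. All CAST/EiJ clean-air mice of set B were titled RNA_101 to RNA_105, while its BD mice were 10 to 12. Within set B of that strain, BD and this title series therefore cannot be told apart.

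The first comparison asked how BD changed the lung of C57BL/6J mice. Genes that defend against oxidants and electrophiles rose. Srxn1, which repairs oxidised peroxiredoxins, went from 26.3 ± 1.89 to 79.9 ± 7.23 CPM (SD), a log2 change of 1.60 ± 0.08 (SE, adjusted p = 3.64e-11). Gclc, the catalytic subunit of the rate-limiting enzyme of glutathione synthesis, rose from 171 ± 24 to 484 ± 65.5 CPM (log2 change 1.5 ± 0.15, adjusted p = 3.75e-06). Aox1, an aldehyde oxidase, rose by 0.97 ± 0.09 on the log2 scale. These changes held within both sets, with Srxn1 at 1.56 in set A and 1.60 in set B. Among the 27 measured targets of NRF2, the transcription factor of the antioxidant response, 19 rose (22 adjusted over the list alone) and their median log2 change was 0.46. The list test gave an adjusted p of 7.96e-18, and 0.0129 with an estimated correlation.

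Some enzymes that conjugate foreign compounds, and some of BD metabolism, rose in the same lungs. Gsta3, a glutathione transferase, rose from 138 ± 19.4 to 334 ± 52.9 CPM (log2 change 1.28 ± 0.14) and Ugt1a6a, a glucuronosyltransferase, rose by 0.98 ± 0.11 on the log2 scale. Of 41 measured conjugation and glutathione genes, 19 rose (20 adjusted over the list alone; median log2 change 0.38, list adjusted p = 1.38e-07, but adjusted p = 0.281 with an estimated correlation). Of 11 measured genes of BD metabolism, 6 rose (7 adjusted over the list alone; median 0.53, list adjusted p = 3.7e-06, and adjusted p = 0.235 with an estimated correlation). They included Ephx1, the microsomal epoxide hydrolase (0.56 ± 0.11, adjusted p = 0.0016), Gstp1 (0.68 ± 0.11) and the alcohol dehydrogenase Adh1 (0.62 ± 0.07). Cyp2e1, a main oxidase of BD, was at 42.1 ± 17.7 CPM in clean air and 63.7 ± 37.7 in BD (adjusted p = 0.482). Cyp1a1, a P450 induced through the aryl hydrocarbon receptor, had the largest rise among the named genes of this comparison, from 9.99 ± 1.09 to 81.6 ± 63.5 CPM (3.03 ± 0.41, adjusted p = 0.000118), and the carboxylesterase Ces1g rose by 2.09 ± 0.22. The call of Ephx1 was lost within set B (log2 change 0.56, adjusted p = 0.0617).

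**Figure D1:**
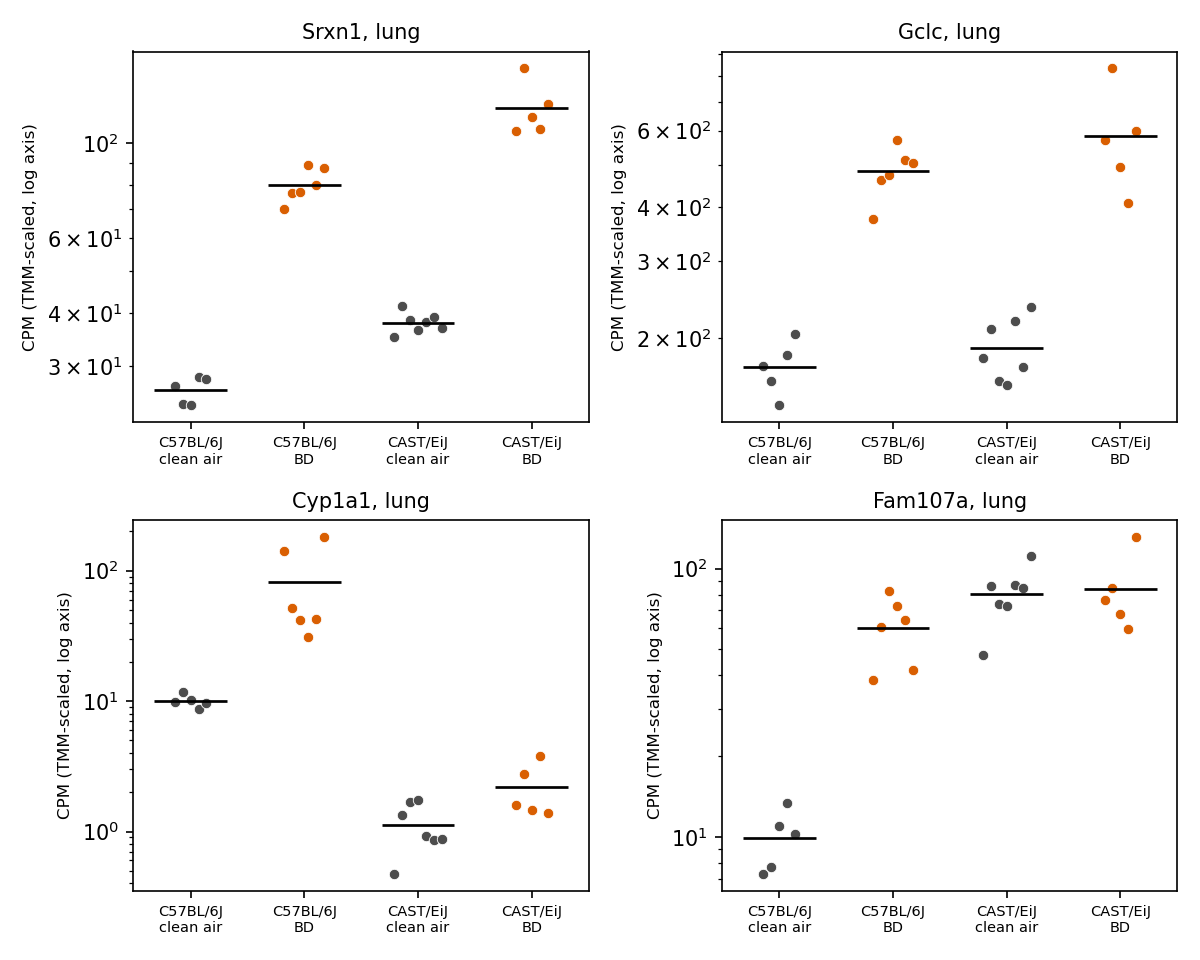
Normalised expression (CPM on a log axis) of Srxn1, Gclc, Cyp1a1 and Fam107a in each lung library, by strain and treatment; points are libraries and bars are group means. Srxn1 means went from 26.3 to 79.9 CPM in C57BL/6J and from 37.9 to 121 CPM in CAST/EiJ, while Fam107a went from 9.93 to 60.0 and from 80.3 to 83.9 CPM.

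Some p53 targets and most measured cell cycle genes also rose. Of 39 measured p53 targets, 16 rose and 2 fell (19 and 3 adjusted over the list alone; median 0.20, list adjusted p = 1.6e-05, and adjusted p = 0.235 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, rose from 13.3 ± 3.38 to 27.6 ± 8.34 CPM (1.05 ± 0.23, adjusted p = 0.0049), Eda2r by 1.38 ± 0.20 and the apoptosis gene Bax by 0.60 ± 0.10. Of 45 DNA repair genes 1 rose (1 adjusted over the list alone), and the list was not called (adjusted p = 0.0516, and 0.593 with an estimated correlation). Mgmt, which removes alkyl groups from guanine, was at 1.58 ± 0.525 and 1.87 ± 0.259 CPM (adjusted p = 0.549). Of 42 cell cycle genes, 25 rose (31 adjusted over the list alone; median 0.49, list adjusted p = 2.01e-13, and adjusted p = 0.377 with an estimated correlation), with Prc1, needed for cytokinesis, at 0.78 ± 0.15 and the replication helicase subunit Mcm7 at 0.36 ± 0.06. The list p-values were reached by 5 of 100 splits of the mice for p53 targets and 7 for the cell cycle. Within set B the calls of Cdkn1a (0.87, adjusted p = 0.231), Eda2r (1.24, 0.0578), Bax (0.52, 0.0896), Prc1 (0.71, 0.089) and Mcm7 (0.36, 0.0701) were lost.

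Some glucocorticoid-responsive genes rose as well. Fkbp5, a chaperone of the glucocorticoid receptor, went from 18.2 ± 4.07 to 88.0 ± 25.5 CPM (2.27 ± 0.31, adjusted p = 0.000118), Zbtb16, a transcription factor gene induced by glucocorticoids, from 80.1 ± 28 to 275 ± 77.7 CPM (1.78 ± 0.26) and the kinase Sgk1 by 0.62 ± 0.10 on the log2 scale. Fam107a rose from 9.93 ± 2.51 to 60.0 ± 17.2 CPM (2.58 ± 0.25). Of 19 measured glucocorticoid and fasting targets, 7 rose and 1 fell (8 and 3 adjusted over the list alone; median 0.50, list adjusted p = 0.00548, and adjusted p = 0.593 with an estimated correlation). The list p was reached by 14 of 100 splits of the mice. Fkbp5 and Zbtb16 held within both sets.

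Most measured B cell markers, class II genes and immediate early genes fell in these lungs. Of 15 measured B cell markers, 13 fell (14 adjusted over the list alone; median -1.33, list adjusted p = 2.33e-12, and adjusted p = 0.478 with an estimated correlation), with the chemokine receptor Cxcr5 going from 16.3 ± 3.11 to 6.25 ± 2.06 CPM (-1.39 ± 0.28, adjusted p = 0.00278). Of 21 T and NK cell markers, 3 fell (11 adjusted over the list alone; median -0.59, list adjusted p = 1.29e-08, and adjusted p = 0.478 with an estimated correlation). Of 13 MHC class II and antigen presentation genes, 8 fell (9 adjusted over the list alone; median -0.54, list adjusted p = 1.26e-07, and adjusted p = 0.478 with an estimated correlation), among them Ciita, the master regulator of class II genes, from 72.0 ± 14.5 to 33.0 ± 9.37 CPM. Of 20 immediate early genes, which cells switch on within minutes of a stimulus, 14 fell (16 adjusted over the list alone; median -0.86, list adjusted p = 9.2e-12, and adjusted p = 0.281 with an estimated correlation), with Egr1 from 57.2 ± 33.3 to 12.4 ± 2.69 CPM (-2.20 ± 0.35). The p-values of these 4 lists were reached by 5, 11, 14 and 14 of 100 splits. Macrophage genes moved both ways: the scavenger receptor Marco rose by 1.57 ± 0.20 and lysozyme Lyz2 by 0.67 ± 0.13, while Csf1r fell by 0.39 ± 0.08 on the log2 scale. Marco and Lyz2 held within both sets; Cxcr5 (-1.38, adjusted p = 0.135), Egr1 (-1.34, adjusted p = 0.19) and Csf1r (-0.43, adjusted p = 0.0711) lost their calls within set B, and Ciita (-0.86, adjusted p = 0.0533) within set A. Rn45s took 6.87 ± 5.4% of counts in clean-air lungs and 1.73 ± 2.16% in BD lungs of this strain (exact permutation test, both sides, p = 0.0433, adjusted p = 0.13 over 6 such comparisons).

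In all, edgeR's quasi-likelihood test called 2283 of 16095 genes in C57BL/6J lung at an adjusted p under 0.05, 1076 higher and 1207 lower in BD, with a median size of 0.48 on the log2 scale. Within set A 1337 genes and within set B 172 genes were called, with median changes of these 2283 genes of 0.50 and 0.43. Without clean-air mouse 4, clean-air mouse 5 or BD mouse 17 the count was 1190, 1200 and 1496.

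In CAST/EiJ lung, genes of the antioxidant response rose, among them Srxn1 and Gclc. Srxn1 went from 37.9 ± 2.05 to 121 ± 17.9 CPM (1.67 ± 0.08, adjusted p = 2.15e-12; 1.75 within set A and 1.62 within set B). Gclc rose from 190 ± 30.9 to 582 ± 160 CPM (1.62 ± 0.14), thioredoxin reductase Txnrd1 from 58.4 ± 7.23 to 139 ± 22.3 CPM (1.25 ± 0.09) and Slc7a11, which imports cystine for glutathione synthesis, from 8.49 ± 3.65 to 49.8 ± 21.4 CPM (2.55 ± 0.35). Of 27 NRF2 targets, 13 rose (15 adjusted over the list alone; median 0.35, list adjusted p = 4.06e-18, and 0.0129 with an estimated correlation). Srxn1, Gclc, Txnrd1 and Slc7a11 held within both sets and with every library left out in turn.

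Other detoxification genes were mixed in CAST/EiJ lung. Gstm1 rose by 0.74 ± 0.08 (adjusted p = 4.04e-06), Ces1g by 1.24 ± 0.19 and Chac1, which degrades glutathione, by 1.43 ± 0.20. Of 41 conjugation and glutathione genes, 8 rose and 1 fell (10 and 1 adjusted over the list alone); their median was -0.07 and their mean -0.21 although the list test pointed up (adjusted p = 0.00175, and 0.593 with an estimated correlation). Ephx1 was at 218 ± 33.7 and 226 ± 26.6 CPM (adjusted p = 0.779). Of 39 p53 targets, 5 rose (6 adjusted over the list alone; list adjusted p = 0.00413, and adjusted p = 0.478 with an estimated correlation), among them Mdm2, which degrades p53, by 0.36 ± 0.06 (adjusted p = 0.00319). Cdkn1a was at 26.2 ± 5.83 and 39.8 ± 11.3 CPM (adjusted p = 0.0893).

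Some airway cell markers were lower in BD in the same lungs. Of 17 alveolar and airway epithelial markers, 4 fell (6 adjusted over the list alone; median -0.27, list adjusted p = 0.00117, and adjusted p = 0.593 with an estimated correlation). All 4 are secretory proteins of the airway lining: Scgb3a2 went from 473 ± 167 to 185 ± 72.8 CPM (-1.35 ± 0.29, adjusted p = 0.0166), and Scgb1a1, Scgb3a1 and Bpifa1 fell by 0.48 ± 0.12, 1.58 ± 0.42 and 2.18 ± 0.60 on the log2 scale. Of 15 ciliated cell markers, 2 fell (9 adjusted over the list alone; median -0.40, list adjusted p = 0.000158, and adjusted p = 0.705 with an estimated correlation), with the ciliary protein Tekt4 at -0.74 ± 0.16. The list p-values were reached by 20 and 21 of 100 splits of the mice for the epithelial and ciliated lists. Of 24 cholesterol synthesis genes, 2 fell (5 adjusted over the list alone; median -0.27, list adjusted p = 5.88e-06, and adjusted p = 0.553 with an estimated correlation). Only Scgb3a2 among these airway genes held within both sets (-2.04 and -0.97). Leaving out 1 library ended the calls of Scgb1a1 (without mouse 9 or 11), Scgb3a1 (7, 9, 11, RNA_104 or RNA_105) and Bpifa1 (7, 9, 11, RNA_101, RNA_104 or RNA_105), with highest adjusted p of 0.0604, 0.0801 and 0.0932. With only mice numbered under 100, the epithelial list pointed up with an adjusted p of 0.689.

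In all, 988 genes were called in CAST/EiJ lung, 621 higher and 367 lower, with a median size of 0.44. Changes were smaller within set A, which held 2 clean-air mice. The 988 genes had median changes of 0.26 within set A and 0.48 within set B, and the sets called 242 and 2708 genes. The sets also differ in their BD mice, and the 988 genes were selected mostly by set B. The 13 called NRF2 targets had medians of 0.88 and 0.82. Without clean-air mouse 1 or 2 the count was 2201 and 1669. Without clean-air mice RNA_101 to RNA_105 in turn it was 392, 492, 459, 268 and 425, and without BD mice 7, 9 and 10 it was 327, 305 and 390.

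The strains were then compared in their response itself. In lung, 2203 genes differed between strains in their BD change, 1154 with a more positive change in CAST/EiJ and 1049 with a more negative one. Fam107a rose from 9.93 ± 2.51 to 60.0 ± 17.2 CPM in C57BL/6J, but stood at 80.3 ± 19.1 CPM in clean air and 83.9 ± 27.9 in BD in CAST/EiJ (difference of log2 changes -2.51 ± 0.32, adjusted p = 0.000368). Adh1 rose in C57BL/6J from 73.4 ± 4.39 to 113 ± 5.49 CPM and was at 162 ± 10.7 and 148 ± 14.9 CPM in CAST/EiJ (-0.74 ± 0.09, adjusted p = 0.000226). Ptgs1, a prostaglandin synthase, went from 82.5 ± 5.24 to 137 ± 10.3 CPM in C57BL/6J and from 72.7 ± 4.31 to 76.1 ± 1.92 in CAST/EiJ (-0.66 ± 0.08). Tcf7, a T cell transcription factor, and Rel, an NF-kappaB subunit of lymphocytes, went the other way, with differences of 1.33 ± 0.21 and 1.55 ± 0.23: Rel was at 17.8 ± 2.67 and 8.30 ± 1.24 CPM in C57BL/6J and at 6.08 ± 1.64 and 8.41 ± 1.31 in CAST/EiJ. Between the lungs of both strains, 118 genes were called in the same direction, 92 higher (41.5 expected of independent lists) and 26 lower (27.5 expected), and 18 in opposite directions. The interaction count was 112 within set A, and 680 within set B. Without clean-air C57BL/6J mice 4, 5 and RNA_106 in turn it was 673, 617 and 3686, without BD mouse 17 of that strain 1043, and without CAST/EiJ clean-air mice 1 and RNA_104 or BD mouse 10 it was 3401, 1364 and 968. The shared count fell to between 70 and 77 without CAST/EiJ BD mouse 7, 9 or 10 or any of clean-air mice RNA_101 to RNA_104. Whether list changes differed between strains was not tested.

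**Figure D2:**
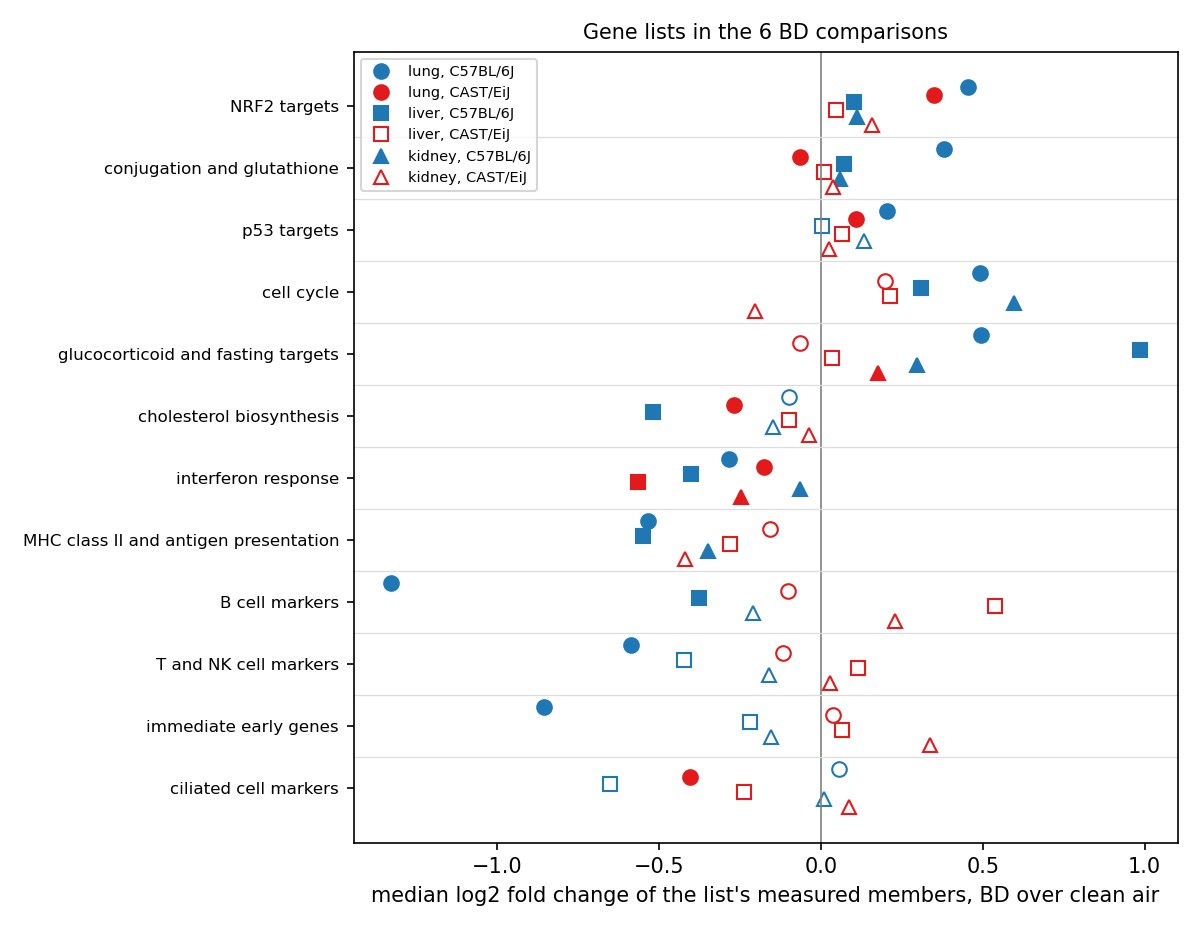
Median log2 fold change (BD over clean air) of the measured members of 12 gene lists in the 6 BD comparisons; colour gives the strain and shape the tissue. Filled symbols mark lists with an adjusted p under 0.05 by the preset-correlation test. NRF2 targets stood at 0.46 and 0.35 in the lungs of C57BL/6J and CAST/EiJ, and B cell markers at -1.33 in C57BL/6J lung. With an estimated correlation the NRF2 calls in both lungs held and the B cell call was lost.

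In C57BL/6J liver, some genes of the glucocorticoid and fasting response were higher in BD. The metallothioneins Mt1 and Mt2, which bind zinc and copper, rose from 50.7 ± 30 to 440 ± 76.6 CPM (3.12 ± 0.43, adjusted p = 0.000685) and from 11.4 ± 7.11 to 144 ± 41.3 CPM (3.66 ± 0.54). Zbtb16 rose from 8.48 ± 2.14 to 63.2 ± 19.1 CPM (2.90 ± 0.35, adjusted p = 0.000404). Lpin1, a phosphatidate phosphatase that also acts as a coactivator, rose from 150 ± 50.8 to 905 ± 263 CPM (2.60 ± 0.34), and Pck1, the rate-limiting enzyme of gluconeogenesis, from 2430 ± 285 to 5370 ± 727 CPM (1.15 ± 0.16). Of 21 measured glucocorticoid and fasting targets, 7 rose (12 adjusted over the list alone; median 0.99, list adjusted p = 1.5e-19, and adjusted p = 0.0533 with an estimated correlation). The glutathione transferases Gstm1 (0.99 ± 0.20) and Gstm3 (1.5 ± 0.29) rose, as did Por, the electron donor of P450 enzymes (1.21 ± 0.26), and Ephx1 (0.57 ± 0.13, adjusted p = 0.032). The call of Ephx1 was lost with any 1 of 7 libraries left out, among them clean-air mice 3 to 6, with a highest adjusted p of 0.0991, and that of Por with 4.

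In the same livers, 3 of 24 cholesterol synthesis genes fell (12 adjusted over the list alone; median -0.52, list adjusted p = 1.58e-10, and adjusted p = 0.377 with an estimated correlation): Mvd of the mevalonate pathway from 11.5 ± 3.56 to 4.81 ± 1.43 CPM (-1.26 ± 0.20, adjusted p = 0.00145), the sterol carrier Stard4 (-0.71 ± 0.12) and squalene epoxidase Sqle (-0.82 ± 0.16), whose call was lost without clean-air mouse RNA_106 (adjusted p = 0.0584). The repressor Bcl6 fell from 43.0 ± 22.5 to 8.25 ± 2.49 CPM (-2.38 ± 0.42) and Xbp1, a regulator of the unfolded protein response, from 186 ± 35.8 to 94.1 ± 11.3 CPM. Of 38 interferon response genes 0 were called by edgeR over all genes, 5 fell adjusted over the list alone, 16 were lower at an unadjusted p under 0.05, and DESeq2 called 0 (median -0.40, list adjusted p = 1.59e-11, and adjusted p = 0.478 with an estimated correlation). Hsd3b5, a male-specific steroid enzyme of mouse liver, fell from 239 ± 60.2 to 84.0 ± 19.1 CPM (adjusted p = 0.025), a call lost with any 1 of 7 libraries left out. The kidney gene Kap was also called lower, but all its clean-air signal came from mouse RNA_106, at 12.9 CPM.

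In all, 128 of 13501 genes were called in C57BL/6J liver, 79 higher and 49 lower. Their median changes were 1.00 within set A and 0.94 within set B, which called 53 and 6 genes on their own, and Zbtb16, Mt1, Lpin1 and Pck1 kept their calls within set A and lost them within set B (2.83, 2.96, 2.64 and 0.87; adjusted p = 0.0587, 0.0923, 0.0719 and 0.113). Mvd (-1.28), Stard4 (-0.67), Gstm1 (0.60), Gstm3 (1.3), Mt2 (3.56), Por (1.15) and Ephx1 (0.19) also lost their calls within set B. Bcl6 (-2.42 and -2.33), Xbp1 (-1.10 and -0.82), Sqle (-0.75 and -0.94) and Hsd3b5 (-1.50 and -1.45) lost theirs within both sets. Cdkn1a was at 0.436 ± 0.142 CPM in clean air and 1.40 ± 0.285 in BD in these livers (adjusted p = 0.075). The count fell to between 63 and 82 without any of the 5 clean-air mice or without BD mouse 14, 16 or 17.

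In CAST/EiJ liver, all 15 called genes were lower in BD, and each was far more abundant in kidney. Kap, an androgen-regulated protein of the proximal tubule, was at 18.3 ± 6.66 CPM in clean-air livers and 0.153 ± 0.158 in BD livers. Umod was at 4.01 ± 1.53 and 0.0302 ± 0.074 CPM, and the phosphate transporter Slc34a1 at 3.36 ± 1.79 and 0.0681 ± 0.0628 CPM. The endocytic receptor Lrp2 fell by 2.36 ± 0.34 on the log2 scale (adjusted p = 0.00262). Of 16 measured proximal tubule markers, 7 fell (11 adjusted over the list alone; median -2.54, list adjusted p = 3.81e-27, and 0.0034 with an estimated correlation). In the kidney libraries Kap averaged 21700 ± 3540 CPM. No gene was called higher by edgeR, while 1276 genes passed an unadjusted p under 0.05 in either direction and DESeq2 called 48 genes. Kap, Umod and Slc34a1 lost their calls within set A (adjusted p = 0.0533 each), with log2 changes of -7.89, -9.72 and -6.57 there beside -6.81, -6.66 and -5.48 over all livers. Slc34a1 lost its call without BD mouse 11 (adjusted p = 0.0512). The count was 3 within set A, 45 within set B and 2 without the livers whose Rn45s share was above 25%.

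**Figure D3:**
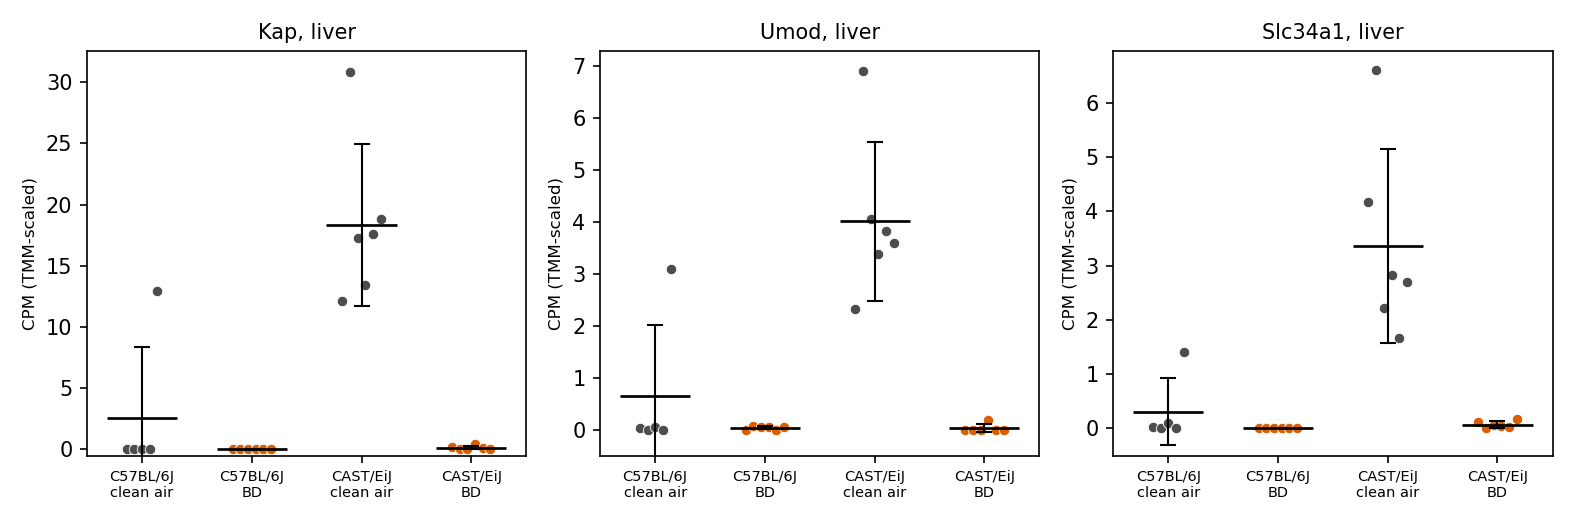
Normalised expression (CPM) of the kidney genes Kap, Umod and Slc34a1 in each liver library, by strain and treatment; points are libraries, bars are means and whiskers are SD. Kap lay between 12.1 and 30.8 CPM in the 6 clean-air CAST/EiJ livers and at 12.9 CPM in 1 clean-air C57BL/6J liver.

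The interferon response list pointed down in BD livers of CAST/EiJ, though edgeR called no single member. Of the 38 measured members, 0 were called by edgeR over all genes, 17 fell adjusted over the list alone, 20 were lower at an unadjusted p under 0.05, and DESeq2 called 5 (median -0.57, list adjusted p = 4.24e-16, and adjusted p = 0.32 with an estimated correlation). In livers of this strain the genes of BD metabolism showed no call by edgeR or DESeq2, and 0 of 12 passed an unadjusted p under 0.05. Cyp2e1 was at 3580 ± 425 CPM in clean air and 3840 ± 258 in BD, and Ephx1 at 383 ± 31.8 and 410 ± 35.9 CPM. Cdkn1a was at 0.425 ± 0.258 and 1.16 ± 0.924 CPM (adjusted p = 0.347). In liver, 5 genes differed between strains in their BD change. Zbtb16 rose in C57BL/6J and stood at 32.2 ± 17.2 CPM in clean air and 40.2 ± 19 in BD in CAST/EiJ (difference of log2 changes -2.58 ± 0.46, adjusted p = 0.0341). Pck1 (-1.18 ± 0.21), the serine dehydratase Sds (-1.27 ± 0.23) and Myo1e (-1.02 ± 0.17) differed the same way, and the tight junction gene Cldn2 the other way (1.36 ± 0.21, adjusted p = 0.0168). DESeq2 called 31 genes for this difference, and the count was 0 within each set. It was 0 without clean-air CAST/EiJ mouse RNA_104, 1 to 3 without C57BL/6J mouse 3, 4, 5, 6, 15 or 17 or CAST/EiJ mouse 2, 9, 10, 11 or RNA_105, and 8 to 12 without C57BL/6J mouse 13 or RNA_106 or CAST/EiJ mouse 12. The strains shared 1 called liver gene, Kap, a kidney gene whose clean-air signal in C57BL/6J came from RNA_106; this count was 0 without any 1 of the C57BL/6J BD mice or clean-air mouse RNA_106, and 2 without CAST/EiJ BD mouse 8.

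In C57BL/6J kidney, Zbtb16 led a short list of 18 genes. It rose from 4.26 ± 2 to 30.5 ± 6.39 CPM (2.87 ± 0.34, adjusted p = 0.000179), and held within set A (3.23) and set B (2.51) and with every library left out. The glucose-6-phosphatase G6pc rose from 541 ± 68.7 to 1110 ± 114 CPM (1.04 ± 0.20), the glutathione transferase Gsta4 from 23.5 ± 4.51 to 41.8 ± 7.71 CPM (0.82 ± 0.15), Ugt1a6a from 21.5 ± 1.98 to 32.5 ± 4.88 CPM (0.59 ± 0.09, adjusted p = 0.0088) and the retinaldehyde dehydrogenase Aldh1a1 from 10.3 ± 1.5 to 17.5 ± 2.66 CPM. Esm1, an endothelial proteoglycan, fell from 57.5 ± 9.78 to 31.8 ± 2.58 CPM and the vascular potassium channel Kcnj8 from 12.1 ± 2.81 to 7.21 ± 0.819 CPM. Cdkn1a was at 1.3 ± 0.14 and 3.29 ± 0.846 CPM (adjusted p = 0.0517). Of 20 glucocorticoid and fasting targets, 2 rose (8 adjusted over the list alone; median 0.30, list adjusted p = 3.7e-06, and adjusted p = 0.235 with an estimated correlation), and of 27 NRF2 targets 1 rose (4 adjusted over the list alone; list adjusted p = 0.00135, and adjusted p = 0.478 with an estimated correlation). The 18 genes, 14 higher and 4 lower of 15048, were sensitive to single libraries: without clean-air mice 4, 6 and RNA_106 in turn 6, 2 and 9 were called, and without BD mice 13, 15, 16 and 17 in turn 200, 66, 10 and 8. Within set A 1 gene was called and within set B 206. G6pc, Esm1 and Kcnj8 lost their calls with 9, 9 and 6 of the 11 libraries left out in turn, though their log2 changes stayed at 0.99 to 1.09, -0.92 to -0.78 and -0.82 to -0.61, Gsta4 with 3, and Aldh1a1 without mouse 6 (adjusted p = 0.0579). Ugt1a6a lost its call within set A (0.50, adjusted p = 0.206). The other 5 lost theirs within both sets, with log2 changes within set B of 0.97 for G6pc (adjusted p = 0.142), 0.90 for Gsta4 (0.0505), 0.69 for Aldh1a1 (0.0624), -0.63 for Esm1 (0.0926) and -0.79 for Kcnj8 (0.0678).

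**Figure D4:**
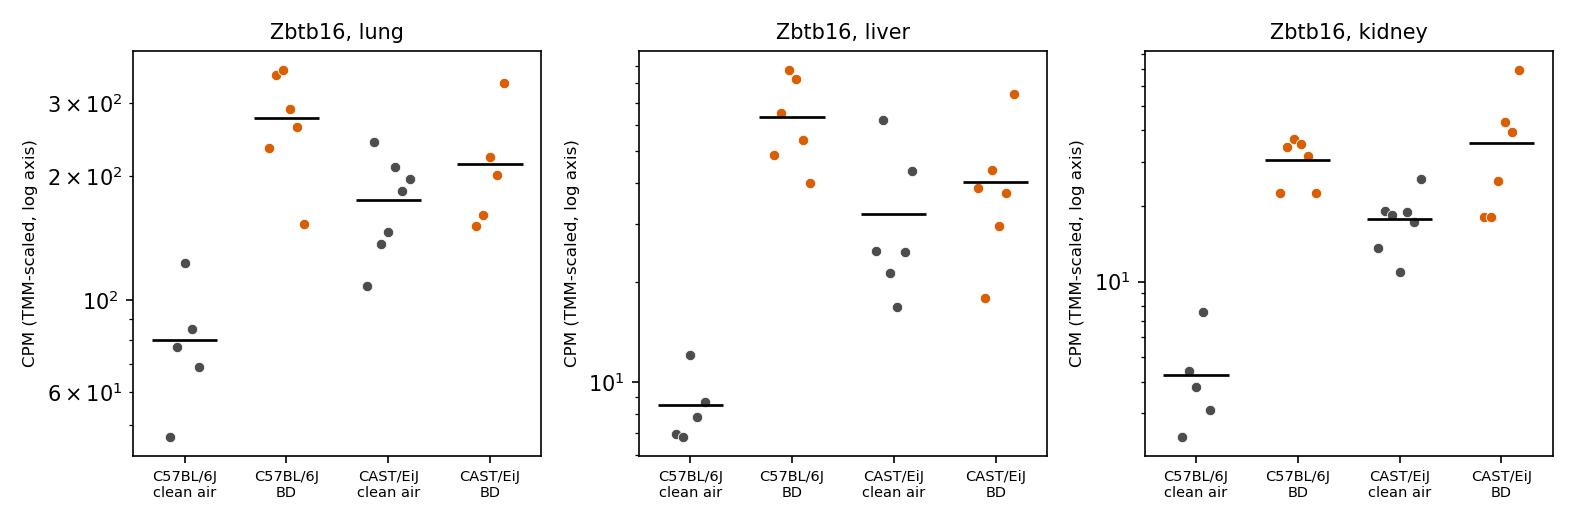
Normalised expression (CPM on a log axis) of Zbtb16 in each lung, liver and kidney library, by strain and treatment; points are libraries and bars are group means. In C57BL/6J the means went from 80.1 to 275 CPM in lung, from 8.48 to 63.2 CPM in liver and from 4.26 to 30.5 CPM in kidney.

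In CAST/EiJ kidney, the metallothioneins rose. Mt2 went from 8.23 ± 2.28 to 23.2 ± 7.3 CPM (1.49 ± 0.19, adjusted p = 0.000268) and Mt1 from 34.4 ± 6.02 to 81.4 ± 18.5 CPM (1.25 ± 0.16), with log2 changes of 1.68 and 1.29 within set A (adjusted p = 0.0714 each) and 1.20 and 1.16 within set B. Of the glutathione transferases, Gsta2 rose from 100 ± 21.7 to 166 ± 18.2 CPM (0.73 ± 0.14, adjusted p = 0.0318), Gsta4 by 0.67 ± 0.13 and Gsta3 by 0.59 ± 0.13. Of 43 conjugation and glutathione genes, 4 rose and 1 fell (7 and 1 adjusted over the list alone), and the list was not called (adjusted p = 0.574). The organic anion transporter Slco1a1 fell from 549 ± 179 to 264 ± 124 CPM (-1.05 ± 0.26, adjusted p = 0.0468). Cdkn1a rose from 2.24 ± 0.717 to 4.25 ± 1.83 CPM (0.90 ± 0.24, adjusted p = 0.0493), a call lost without any library but that of mouse 1 or 9 (log2 change 0.71 to 1.06, highest adjusted p = 0.112) and within each set (1.61 and 0.45). Mgmt and Cyp2e1 had an adjusted p of at least 0.313 and 0.243 in each of the 6 BD comparisons. Of 20 glucocorticoid and fasting targets, 2 rose (5 adjusted over the list alone; list adjusted p = 0.00468, and adjusted p = 0.509 with an estimated correlation), and of 14 endothelial markers 1 rose (7 adjusted over the list alone; list adjusted p = 0.00198, and adjusted p = 0.593 with an estimated correlation). The test called 276 genes, 207 higher and 69 lower, or 551 and 803 by DESeq2. With RLE scaling 120 were higher and 141 lower. Within set A, with 2 clean-air mice, 1 gene was called, and within set B 1876; without clean-air mouse 1 or BD mouse 9 the count was 1948 and 898, and without any other library of the 13 it was 2 to 19. Mt1 and Mt2 kept their calls with each of the 13 libraries left out, whereas Gsta2, Gsta3, Gsta4 and Slco1a1 lost them in 9, 10, 10 and 11 cases, with log2 changes of 0.66 to 0.78, 0.52 to 0.65, 0.60 to 0.72 and -1.33 to -0.91. Within set A these 4 also lost their calls (0.73, 0.65, 0.74 and -0.72), and Gsta3 within set B (0.44, adjusted p = 0.0532). Aldh1a1 was the 1 gene whose change differed between strains in kidney (difference -1 ± 0.16, adjusted p = 0.0244), at 10.3 ± 1.5 and 17.5 ± 2.66 CPM in C57BL/6J and at means of 726 and 603 in CAST/EiJ; 1909 genes passed an unadjusted p under 0.05 for this difference and DESeq2 called 12. Within set A 0 and within set B 149 genes were called. The count was 4 without C57BL/6J clean-air mouse RNA_106 and 0 without C57BL/6J mouse 3, 4, 5, 6, 16 or 17 or CAST/EiJ mouse 7, RNA_101, RNA_103, RNA_104 or RNA_105. Rn45s took 5.37 ± 5.43% of counts in clean-air and 0.77 ± 0.586% in BD kidneys of CAST/EiJ (exact permutation test, both sides, p = 0.0227, adjusted p = 0.13). The strains shared 2 called kidney genes, both higher in BD, and 0 to 5 with a library of either strain left out.

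Whether the response differed between tissues was tested within each strain. In C57BL/6J, 391 of 16634 genes changed differently over lung, liver and kidney, with the largest change in lung for 177, in liver for 191 and in kidney for 23. Srxn1 had log2 changes of 1.60 ± 0.08 in lung, -0.10 ± 0.14 in liver and 0.22 ± 0.07 in kidney (adjusted p = 8.86e-09). Lpin1 had 0.50 ± 0.19, 2.60 ± 0.34 and 0.23 ± 0.14 (adjusted p = 3.81e-07), and the mitochondrial coactivator Ppargc1a -0.58 ± 0.23, 1.54 ± 0.42 and 0.17 ± 0.13. In CAST/EiJ, 39 of 16499 genes differed. Srxn1 had 1.67 ± 0.08, -0.19 ± 0.13 and 0.10 ± 0.07 (adjusted p = 1.08e-10) and Gclc 1.62 ± 0.14, -0.04 ± 0.11 and -0.11 ± 0.16 (adjusted p = 1.81e-07). The next genes, Cdh16, Fxyd2, Slc5a12 and Slc12a1, are kidney transcripts near 0 CPM in BD livers. Because equal numbers in different tissues were read as the same mouse, the test was repeated with the mouse as a replicate block: 1030 genes were called in C57BL/6J and 32 in CAST/EiJ. Without C57BL/6J mice 4, 5, 13, 16 and 17 in turn the C57BL/6J count was 162, 179, 722, 192 and 201, and without CAST/EiJ mouse 1 the other was 63.

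Genes called in more than 1 tissue were then counted. In C57BL/6J, 27 genes were called in the same direction in lung and liver (20 higher, 5.49 expected of independent lists, and 7 lower, 3.01 expected), 10 in lung and kidney (9 higher and 1 lower), and 3 in liver and kidney, all higher. In CAST/EiJ, 55 genes were shared by lung and kidney (53 higher, 8.27 expected, and 2 lower), and 1 by lung and liver, the kidney transcript Fxyd2 (-1.38, adjusted p = 0.0438, and -5.11, adjusted p = 0.00452). Liver and kidney of that strain shared 0 genes by edgeR and 14 by DESeq2. Within set A and set B, C57BL/6J lung and liver shared 11 and 0 genes and CAST/EiJ lung and kidney 0 and 835. With a library left out in turn, C57BL/6J shared 13 to 40 genes in lung and liver, 2 to 59 in lung and kidney and 1 to 10 in liver and kidney. In lung and liver the count was 13 to 17 without the liver of mouse 3, 4, 6, RNA_106, 14, 15 or 17, and 18 without that of mouse 16. In lung and kidney it was 59 and 21 without the kidney of mouse 13 or 15, and 2 to 6 without that of mouse 3, 4, 6, RNA_106, 16 or 17. In liver and kidney it was 10 without the kidney of mouse 13, 1 without that of mouse 4, 6 or RNA_106, and 2 without that of mouse 3, 14, 16 or 17 or the liver of mouse 3, 4, 6, 13, 16, 17, 18 or RNA_106. In CAST/EiJ lung and kidney it was 207 and 115 without the kidney of mouse 1 or 9, and 1 to 5 without any other kidney. Without the lung of mouse 1 it was 91, and without that of mouse 7, 9, 10, RNA_101, RNA_102, RNA_103, RNA_104 or RNA_105 it was 12 to 31. With RLE scaling it was 31, with no filter 7, with DESeq2 219, with 1 surrogate variable 213, with the set as covariate 324, with mice under 100 it was 1, and at an adjusted p under 0.1 it was 345. In C57BL/6J, DESeq2 gave 58, 45 and 13 genes for lung and liver, lung and kidney, and liver and kidney, and 1 surrogate variable 33, 19 and 5. Fxyd2 was no longer shared without any BD lung or the lung of RNA_101, RNA_102, RNA_104 or RNA_105, and the shared count was 5 without the BD liver of mouse 8 and 2 without the clean-air liver of mouse 2.

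The strains differed widely in clean air. In lung 9945 genes differed (5205 higher and 4740 lower in CAST/EiJ), in liver 5666 (2811 and 2855) and in kidney 6687 (3215 and 3472). Iigp1, an interferon-induced GTPase, was at 85.8 ± 20.7 CPM in lung, 384 ± 63.6 in liver and 35.4 ± 8.2 in kidney of C57BL/6J and at 0.122 ± 0.102, 0.116 ± 0.23 and 0.0303 ± 0.065 CPM in CAST/EiJ. The urinary protein Mup20 was at 7510 ± 2350 CPM in C57BL/6J liver and 2.06 ± 3.06 in CAST/EiJ liver. The sulfotransferase Sult3a1 and Cyp3a41a, both known as female-biased in mouse liver, were at 0.35 ± 0.282 and 0.135 ± 0.0482 CPM in C57BL/6J males and at 2030 ± 416 and 247 ± 86.8 CPM in CAST/EiJ males. In kidney Cyp2a4, a P450 of steroid hydroxylation, was at 497 ± 86.6 and 0.312 ± 0.161 CPM. The labels give 1 genome build for all libraries, and whether CAST/EiJ reads were counted on a copy adjusted to that strain is not given in the sources used here. A CAST/EiJ gene that is absent from the reference or differs in sequence can read low, and members of the Mup, Sult3a and Cyp families share reads.

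Between strains every list call was lost with an estimated correlation. Of 38 interferon response genes 26 were lower and 4 higher in CAST/EiJ lung, and 26 and 3 in liver; of 37 in kidney 27 and 3 (list adjusted p = 0.000338, 5.35e-05 and 1.27e-07, and 0.851, 0.82 and 0.82 with an estimated correlation). All 15 measured B cell markers and 20 of 21 T and NK cell markers were lower in CAST/EiJ lung (median -1.67 and -1.86, list adjusted p = 5.35e-05 and 4.42e-08), as were 10 of 13 class II genes in lung and 11 of 11 in kidney (list adjusted p = 0.000781 and 6.22e-05, and 0.82 for each of these 4 with an estimated correlation). In liver, 14 of 21 glucocorticoid and fasting targets were higher in CAST/EiJ (median 1.08, list adjusted p = 0.00123) and 13 of 20 fatty acid synthesis genes lower (list adjusted p = 0.00362, and 0.82 for both with an estimated correlation). In kidney, 30 of 42 cell cycle genes were higher (list adjusted p = 0.00123, and 0.997 with an estimated correlation). Adjusted over the list alone the counts were the same or higher by at most 3 genes. With only mice numbered under 100, the liver and kidney counts were 3238 and 3816.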

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

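The tests of whether BD lowered kidney genes in liver cells, of clean-air mouse numbers, and of lymphoid tissue in some clean-air lungs were chosen after the result was seen. Libraries standing apart from their group were sought in 310 cases, each 1 measure or gene in 1 group of 5 to 7 libraries. Chance alone marks about 1 in 20; 28 were marked.

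The first pattern is the kidney transcripts in CAST/EiJ clean-air livers, where Kap stood apart in mouse 2 at 30.8 CPM, with Lrp2 at 11.6 CPM and Gpx3 at 15 CPM in the same liver. Kidney RNA in the liver libraries would give each kidney gene the same share of its kidney level, and 83.3% of 42 kidney-abundant genes lay within 2 times the median share of 0.0777%. All 6 CAST/EiJ clean-air livers (0.0755 to 0.139%) and C57BL/6J mouse RNA_106 carried it, against at most 0.00542% in BD livers, and in that mouse Kap stood apart at 12.9 CPM. That 15 of 15 called genes were over 50 times higher in kidney than in BD livers does not bear on a lowering of these genes in liver cells by BD, since any kidney-abundant gene near 0 in BD livers passes that test. Of the 42 genes, 39 were higher in clean-air livers. Across genes the log2 excess and the log2 kidney level had a Pearson r of 0.62, with genes lacking an excess set to a floor. The similar share of most of these genes would follow from kidney RNA that may have entered the libraries at dissection or later. Which step was not tested.

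The second pattern is that the CAST/EiJ lung and kidney calls changed with the clean-air mice used. Median changes of the called genes within number set A, with clean-air mice 1 and 2, were 0.548 of those within set B in lung and 0.491 in kidney. By limits chosen after the result was seen, the kidney ratio only just counted for clean-air mice RNA_101 to RNA_105 differing from mice 1 and 2. The lung ratio counted neither for nor against it. The ratio cannot decide this in either tissue, because the sets also differ in their BD mice. Set A has 2 clean-air libraries, and the genes were selected mostly by set B. A biological difference between the mice stays open and was not tested.

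The third pattern is the lower B cell markers in BD lungs of C57BL/6J. Lymphoid tissue in some clean-air lungs would lift a few of them, but 6 of 6 BD lungs lay below every clean-air lung. The gap was small, with a mean log2 level of 3.74 in the highest BD lung and 3.86 in the lowest clean-air lung. Most of these markers had been called lower in the same libraries, so the separation largely restates those calls. It does not address lymphoid tissue carried by all clean-air lungs. The number set is argued against as the cause, since the smaller within-set median fall was -1.11 beside -1.37 in the other set. A lower share of B cells or lower expression per cell may each give this, and bulk RNA does not tell them apart; an effect of BD is a hypothesis.

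Rn45s stood apart as the highest of its group in lung in C57BL/6J BD mouse 15 (6.03%), in liver in CAST/EiJ BD mouse 7 (45.3%), and in kidney in C57BL/6J BD mouse 16 (12%), C57BL/6J clean-air mouse 4 (19.2%) and CAST/EiJ clean-air mouse 2 (16.6%). The liver library of CAST/EiJ clean-air mouse RNA_104 had the highest total count of its group, 42.1 megacounts.

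Among C57BL/6J lungs the highest libraries apart from their group were BD mouse 18 for Ces1g (49.9 CPM), clean-air mouse 5 for Fkbp5 (25.2), clean-air mouse RNA_106 for Eda2r (7.55) and BD mouse 13 for Nr1d1 (60.6). Among CAST/EiJ lungs these were clean-air mouse 1 for Slc7a11 (16 CPM), clean-air mouse 2 for Scgb1a1 (8680), BD mouse 10 for Scgb3a1 (120) and clean-air mouse RNA_101 for Mgmt (6.76). In C57BL/6J liver they were BD mouse 13 for Mt2 (222 CPM), BD mouse 18 for Cyp2a4 (59.8), Mvd (7.65) and Kap (0.0503), and clean-air mouse 5 for Hsd3b5 (343). The call of Cyp2a4 in that strain was lost without mouse 18 or any 1 of the 5 clean-air mice, with 1 surrogate variable and within both sets. In CAST/EiJ liver, BD mouse 10 was highest for Umod (0.181 CPM) and BD mouse 7 lowest for Sult3a1 (485). In kidney, C57BL/6J clean-air mouse 6 was highest for Ugt1a6a (25 CPM), CAST/EiJ clean-air mouse 1 for Cdh5 (27.2) and CAST/EiJ clean-air mouse RNA_105 for Kcnc4 (9.11).

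The BD change differed between strains by a test of the difference itself in lung for Amigo1 (0.83), Rel (1.55), Nhsl1 (1.08), Tcf7 (1.33), Tbcel (0.53), Ptgs1 (-0.66), Adh1 (-0.74), Fam107a (-2.51), Mettl21e (-1.57) and Stt3b (-0.69), as log2 differences, CAST/EiJ minus C57BL/6J. In liver it differed for Cldn2 (1.36), Myo1e (-1.02), Zbtb16 (-2.58), Pck1 (-1.18) and Sds (-1.27), and in kidney for Aldh1a1 (-1).

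The BD change differed between tissues in C57BL/6J for Srxn1 (adjusted p = 8.86e-09), Pptc7 (9.25e-08), Tbc1d8 (1.14e-07), Slc25a51 (1.14e-07), Ppargc1a (2.04e-07) and Lpin1 (3.81e-07). In CAST/EiJ it differed for Srxn1 (1.08e-10), Cdh16 (1.63e-08), Gclc (1.81e-07), Fxyd2 (2.99e-07), Slc5a12 (3.15e-07) and Slc12a1 (3.51e-07). Of the genes without a value in CAST/EiJ, 18 had a mean of at least 1 CPM in C57BL/6J.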

How the results depend on the processing

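The number-set covariate, the fits within sets and liver without libraries above 25% Rn45s were chosen after seeing the data; the other alternatives were fixed in advance, and the cause of each shift was not tested.

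DESeq2 called 1704 genes in CAST/EiJ lung, 337 and 48 in C57BL/6J and CAST/EiJ liver, 31 for the liver strain difference in response, 150 and 1354 in C57BL/6J and CAST/EiJ kidney and 12 for the kidney difference. It gave 950 and 183 for the tissue interaction in C57BL/6J and CAST/EiJ, and 181, 3 and 16 genes shared between strains in lung, liver and kidney. With 1 surrogate variable the liver difference was 8, kidney 44 and 1554, and genes shared in liver 0 and kidney 10. Without the low-count filter CAST/EiJ kidney gave 33 and 1 shared kidney gene. With the replicate block (paired by mouse) the C57BL/6J tissue interaction gave 1030.

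With only mice under 100 the counts were 497 in CAST/EiJ lung, 227 for the lung difference, 73 in C57BL/6J liver, 2 for the liver difference, 1 and 2 in kidney, 0 for the kidney difference, 260 for the CAST/EiJ tissue interaction, 3238 and 3816 between strains in clean-air liver and kidney, and 65, 0 and 0 shared. With the set as covariate they were 1555 in CAST/EiJ lung, 227 in C57BL/6J liver, 52 and 1186 in kidney and 10 shared in kidney.

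Within set A the counts were 1337 and 242 in lung, 112 for the lung difference, 53 and 3 in liver, 0 for the liver difference, 1 and 1 in kidney, 0 for the kidney difference, 3340 and 4396 between strains in liver and kidney, and 22, 0 and 0 shared. Within set B they were 172 and 2708 in lung, 680, 6 and 45 in liver, 0, 206 and 1876 in kidney, 149, and 32, 0 and 18 shared, in the same order. Without livers above 25% Rn45s, CAST/EiJ liver gave 2 and shared liver genes 0. At an adjusted p under 0.1, 245 lung and 15 kidney genes were shared.

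Leaving out each library in turn gave 1190 to 2955 and 268 to 2201 genes in lung, 617 to 3686 for the lung difference, 63 to 189 and 12 to 20 in liver, 0 to 12 for the liver difference, 2 to 200 and 2 to 1948 in kidney, and 0 to 4 for the kidney difference. The tissue interaction gave 162 to 722 and 36 to 63, shared genes 70 to 154, 0 to 2 and 0 to 5, and strain differences 9075 to 10236, 5079 to 5816 and 5938 to 6924.

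With an estimated correlation, 1 list was called in each lung and in CAST/EiJ liver and 0 in the other 6 comparisons; with mice under 100, 16, 14 and 15 lists were called in CAST/EiJ lung, CAST/EiJ liver and the lung strain difference. Direction turned for Kap in C57BL/6J liver, where leaving out each library in turn gave -8.89 to 1.14 on the log2 scale: 1.15 on the log2 scale with mice under 100 (adjusted p = 0.89), 0 within set A (adjusted p = 1) and 1.14 without clean-air mouse RNA_106 (adjusted p = 0.888). With mice under 100 it also turned for airway epithelial markers in CAST/EiJ lung (adjusted p = 0.689), clock genes (0.998) and erythroid markers (0.867) in CAST/EiJ liver, and adrenal markers in CAST/EiJ kidney (0.588). Of 93 list calls, RLE scaling kept 92, 1 surrogate variable 91, no filter 89, the set as covariate 83, mice under 100 kept 70 (19 lost and 4 turned) and the estimated correlation 3.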

Other observations

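The tests of the glucocorticoid list and of clock genes were chosen after the result was seen. Markers of neighbouring tissue varied among libraries. In CAST/EiJ kidney, 4 of 5 adrenal markers were lower in BD adjusted over the list alone (median -3.02, list adjusted p = 0.0339, and adjusted p = 0.756 with an estimated correlation); edgeR called 0 over all genes, 4 passed an unadjusted p under 0.05 and DESeq2 called 1. In C57BL/6J liver, 10 of 13 skeletal muscle markers were higher in BD adjusted over the list alone (median 4.07, list adjusted p = 0.00236, and adjusted p = 0.814 with an estimated correlation); edgeR called 0 over all genes, 10 passed an unadjusted p under 0.05 and DESeq2 called 1. The list p of each was reached by 52 and 45 of 100 splits. Krt13 and Krt4, keratins of stratified linings such as the oesophagus, ran from 0 to 1060 and from 0.12 to 1180 CPM among lung libraries, highest in CAST/EiJ BD mouse 11. Alb reached 836 CPM and Kap 52.7 CPM in the lung library highest for each.

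A hypothesis is that the glucocorticoid list reflects a change of the whole C57BL/6J mouse. The list's mean level was higher in BD mice in 3 of 3 tissues, by 0.50 in lung, 1.27 in liver and 0.41 in kidney on the log2 scale (exact permutation test, p = 0.00216 and adjusted p = 0.00607 each, over 12 comparisons). In CAST/EiJ it was higher in kidney by 0.33 (adjusted p = 0.00607), with -0.08 in lung (0.677) and 0.17 in liver (0.613). Clean-air CAST/EiJ mice stood above clean-air C57BL/6J mice by 0.60, 1.03 and 0.32 (adjusted p = 0.00607, 0.00866 and 0.0108). BD C57BL/6J mice differed from clean-air CAST/EiJ mice by only -0.10, 0.23 and 0.09 (adjusted p = 0.658, 0.335 and 0.335). The clean-air C57BL/6J mice were thus the group with the lowest level in each tissue. Both the BD rise in that strain and the strain difference in clean air rest on them. The list had already been called higher in BD in these 3 tissues of C57BL/6J, so the levels restate those calls. Each of those calls was lost with an estimated correlation. A systemic change, such as stress or lower food intake, stays open; neither was measured.

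A further hypothesis is that tissues of BD and clean-air C57BL/6J mice were taken at another time of day. Over 20 clock genes the mean absolute log2 change was 0.42, which 1 of 100 splits reached (highest other 0.37), but any real difference between the groups can raise this size. The mean r of 0.57 between tissues was reached by 28 of 100 splits, so sampling time stays open.

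Other splits of the mice, 100 with the real one, were counted for each number of genes. No other split called as many genes for C57BL/6J lung (2283, highest other 1274, 1 split as large), the lung difference between strains (2203, 432, 1) and C57BL/6J liver (128, 92, 1). Nor did any for strain differences in clean air in lung (9945, 6734, 1), liver (5666, 1455, 1) and kidney (6687, 3285, 1). The same holds for the C57BL/6J tissue interaction (391, 195, 1). A value of 1 of 100 is the lowest possible, and these values were not adjusted for the number of counts read. With 1 library or mouse left out, the lowest counts in C57BL/6J were 1190 in lung, 63 in liver and 162 for the tissue interaction. Each is below the highest other split. For the liver difference (5, 192, 4) other splits called up to 192 genes, so chance is not excluded there. By count it cannot be excluded for CAST/EiJ liver (15, 578; 5), C57BL/6J kidney (18, 976; 5), the kidney difference (1, 499; 5) and the CAST/EiJ tissue interaction (39, 1518; 10). In CAST/EiJ liver the p of the proximal tubule list was reached by 1 of 100 splits, the real one. No other split came as low (smallest other p = 1.25e-20 by camera with the preset correlation). This list was 1 of 39 tested there, and 1 of 100 is the lowest value possible, so this alone does not exclude chance. For CAST/EiJ lung (988, 1532; 3) and kidney (276, 716; 2) few splits of all 100 were as large. Of those 100, however, 3 others also had every CAST/EiJ clean-air mouse titled RNA_101 to RNA_105 in the clean-air group, and these called 409, 1532 and 1009 genes in lung and 716, 27 and 0 in kidney. With these mice kept together chance is therefore not excluded for either. Splits that called several times the real count point to a structure of the samples, such as the number sets.

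The p of a single list was reached by 1 of 100 splits for NRF2 targets in both lungs and BD metabolism in C57BL/6J lung, 2 and 4 for conjugation genes in C57BL/6J and CAST/EiJ lung, and 13 each for p53 targets and cholesterol synthesis in CAST/EiJ lung. In C57BL/6J liver it was reached by 1 for glucocorticoid and fasting targets, 4 for cholesterol synthesis and 7 for interferon response, and in CAST/EiJ liver by 1 for interferon response. In C57BL/6J kidney it was reached by 1 for glucocorticoid and fasting targets and 6 for NRF2 targets, and in CAST/EiJ kidney by 10 for the former and 11 for endothelial markers.

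For the number of lists called, few splits were as large for C57BL/6J liver (17, highest other 20, 3 splits as large, median of the others 10). With an estimated correlation 0 lists were called there, so chance is not excluded. Nor is it for C57BL/6J lung (16, 23, 11), CAST/EiJ lung (9, 18, 67) or CAST/EiJ liver (8, 16, 48). The same holds for C57BL/6J kidney (10, 18, 49) and CAST/EiJ kidney (9, 18, 29). It also holds for the strain differences in lung (7, 22, 83), liver (9, 17, 35) and kidney (8, 13, 40).

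For shared genes the counts say little, because the other splits called a median of 0 genes and so had few to share. They were 118 between strains in lung (highest other 0; 1 split as large), 1 in liver (0; 1) and 2 in kidney (0; 1), in C57BL/6J 27 for lung and liver (5; 1), 10 for lung and kidney (32; 2) and 3 for liver and kidney (1; 1), and in CAST/EiJ 1 for lung and liver (7; 3), 55 for lung and kidney (5; 1) and 0 for liver and kidney (1; 100). The correlation of the changes over all genes does not depend on calls. Between strains it was 0.13, 0.12 and 0.24 in lung, liver and kidney, which 20, 27 and 8 of 100 splits reached, so chance cannot be excluded. In C57BL/6J it was 0.14, 0.22 and 0.17 for lung and liver, lung and kidney, and liver and kidney (24, 11 and 51 splits), and in CAST/EiJ 0.27, 0.33 and 0.44 (1, 2 and 7 splits).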
